A study of Homo sapiens with 24 samples.

How the data were processed

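Polyadenylated RNA of A549 cells was measured by sequencing in 24 libraries, 12 per experiment. Per the labels' protocols, cells were transfected in suspension with a pool of siRNAs against TAOK2 or a control siRNA at 30 nM using a lipid reagent, or treated with DMSO or compound 2. RNA was extracted with Trizol, had an integrity number above 6, and was sequenced as paired reads of 150 bp to at least 100000000 reads per library. The dose and duration of compound 2 are not given in the sources used here. For the fractionation experiment, total, nuclear and cytoplasmic RNA were taken from cells with control or TAOK2 siRNA.

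The deposited values are transcript abundances in TPM, which the authors computed with kallisto against transcripts of GRCh38.p14, per the submitters' processing notes; the kallisto version is not given in the sources used here. Both tables list 188753 transcripts, and every library sums to 1000000 TPM, so read totals are not kept and no counting interval can be given. TPM is a share of a fixed total: a rise of one class of RNA lowers all others. Transcript identifiers were matched to genes of GENCODE 29, which covered 169797 transcripts (89.96%) and, in each library, 97.0% to 98.3% of TPM. TPM was summed to 35579 genes; unmatched transcripts were left out of the gene tests and tested on their own. The nuclear noncoding RNAs MALAT1 and NEAT1 have no matched transcript in the deposited values, so they could not serve as nuclear markers.

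Libraries were grouped, and assigned to batches, by their labels. In the whole-cell experiment these are control siRNA, TAOK2 siRNA, DMSO and compound 2, with 3 libraries each in batches A, B and C. Titles of these libraries all carry the word mock, and those of the fractionation experiment do not. In the fractionation experiment they are both siRNAs in total, nuclear and cytoplasmic RNA, with 2 libraries each in batches 1 and 2. Pairing by batch was checked on residuals after removing group means: libraries of the same batch correlated at 0.531 to 0.837 in the fractionation experiment, where 12 of 12 libraries matched their own batch best, and at -0.302 to 0.639 in the whole-cell experiment, where 11 of 12 did and 12 of 18 pairs of the same batch were over 0.1. With 2 libraries per group in the fractionation experiment, the residuals of a group mirror each other, so its 12 matches are not independent. Control siRNA and DMSO libraries of batches A, B and C correlated at 0.278, -0.302 and -0.0263 on such residuals. Control siRNA of batch B correlated at -0.175, -0.262 and -0.302 with TAOK2 siRNA, compound 2 and DMSO of its own batch. With those of batch A it correlated at 0.361, 0.339 and 0.339, so the pairing of that library is doubtful. Values with batch as a block are therefore given beside results whose call the block changes, or whose count of calls, or of list members passed (up plus down), it moves by more than 1.5 times.

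Genes with a mean of at least 1 TPM over the 12 libraries of a table were tested with limma 3.58.1 (statmod 1.5.0) in R 4.3.3 on log2(TPM + 1). A linear model with group means over all 12 libraries was followed by empirical Bayes moderation with trend and robust settings and by Benjamini-Hochberg adjustment at 0.05 within each comparison. Comparisons were TAOK2 siRNA minus control siRNA, compound 2 minus DMSO, the difference of these, control siRNA minus DMSO, knockdown in total, nuclear and cytoplasmic RNA, nuclear minus cytoplasmic RNA in control cells, and the effect of knockdown on that ratio. Errors of log2 changes are moderated standard errors, and errors of levels are standard deviations. Transcript usage was tested with limma on the log2 odds of a transcript within its gene, with 0.5 TPM added, and reported as percent shares.

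Fixed gene lists, 37 with 1243 entries of which 1207 were found, covered RNA processing, signalling, stress, cell division, metabolism and markers of other cell types. Lists with at least 5 measured genes were tested with camera in limma at a preset correlation of 0.01, with an estimated correlation and fry given beside it; fry asks whether the genes of a list move on balance in one direction. Counts of list members that passed are given over all genes tested and adjusted over the list alone. The list of nuclear-retained noncoding RNAs had 0 of 15 members in the tables and was not tested. Leukocyte markers had 5 measured genes, 1 higher and 2 lower under knockdown (camera adjusted p = 0.356), and fibroblast and endothelial markers had 8 measured in the fractionation experiment and fewer than 5 in whole cells.

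Named genes follow a rule: the 10 largest rises and 10 largest falls for knockdown and compound 2, and the 5 and 5 largest for the fractionation comparisons and transcript usage, among those with adjusted p under 0.05, a mean of at least 5 TPM, no clone name and the same sign in every batch. To these were added TAOK1, TAOK2 and TAOK3, up to 4 members of each list with the smallest adjusted p, and GAPDH, ACTB and MT-CO1 as fraction markers; where nothing passed, the 3 and 3 with the smallest p are given as values. Groups, comparisons, tests, lists, this rule and the alternatives listed next were fixed before the data were examined. For the difference of responses and the controls, which the rule does not name, the 10 and 10 were taken as well, a choice made after the data were in hand. Some genes that meet the rule are not named in the text.

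Shares of TPM in retained-intron and nonsense-mediated decay transcripts, by GENCODE transcript type, were compared with exact permutation tests, 2-sided. The alternatives were a pseudocount of 0.1, no filter, a filter at 5 TPM, median-centred log values, only the compared groups in the fit, moderation without trend or robust settings, batch as a block, each library left out in turn, camera with an estimated correlation, and shares without mitochondrial genes. Added after seeing the data were TPM rescaled without mitochondrial genes and combinations of the block with median-centring, with that rescaling, with the pseudocount of 0.1, in the fractions with each library left out and, for the fraction lists, with an estimated correlation.

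The gene test was tested on simulated data with the spread that these libraries keep once batch is taken out as a block. The main fit leaves batch differences in its spread, so recovery without a batch shift can overstate what it finds here. For whole-cell knockdown (13106 genes) the gene test recovered 55.2% of genes given a log2 change of 0.5, 95.5% at 1 and 100% at 2. It made 12 false calls. A batch shift was then added, of a size chosen for the simulation and not estimated from these libraries. On those data the recovered shares were 0%, 17.9% and 78.8% with 0 false calls, and 53.7%, 97.0% and 100% with 16 when batch was a block. For nuclear knockdown (13751 genes, 2 libraries per group) it recovered 10.4%, 64.2% and 84.8% with 4 false calls. With a batch shift of the same size these were 0%, 0% and 28.8% with 0, and 5.97%, 56.7% and 84.8% with 2 when batch was a block. In usage, 200 of 200 transcripts given a 4-fold change, of 41078, were recovered, with 34 false calls in other genes. There every transcript had the same noise, 0.5 times the median residual SD of usage, and no batch shift was added. That recovery therefore does not carry over to transcripts with a larger spread. Tables were prepared in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.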

Results

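Polyadenylated RNA of A549, a human lung adenocarcinoma cell line, was sequenced in 24 libraries from 2 experiments. In the whole-cell experiment, cells received control siRNA, siRNA against the kinase gene TAOK2, the vehicle DMSO or compound 2, with 3 libraries per group. Compound 2 is known here only by that code name. The labels give it as an inhibitor of TAOK2 kinase activity, with no dose or time. In the fractionation experiment, cells with control or TAOK2 siRNA gave total, nuclear and cytoplasmic RNA, with 2 libraries per group. The fractions share their batches, so agreement between fractions is not independent replication. Each library is given in TPM, transcript abundances scaled to a fixed total per library, which keep no read total. The depth per library is therefore unknown beyond the stated minimum of 100000000 reads. Replicates of a group correlated across genes at r = 0.984 to 0.997 in the whole-cell experiment and at 0.928 to 0.970 in the fractions. The first principal component of the whole-cell libraries held 70.9% of the variance and set the compound 2 libraries apart from all others. In the fractions it held 63.1%.

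TAOK2 (ENSG00000149930, GRCh38 chromosome 16, 29973641 to 29992261, forward strand), the gene that the siRNA targets, was lower with its siRNA in every batch of both experiments. Whole cells with control siRNA held 40.3, 38.2 and 34.3 TPM of TAOK2 RNA in batches A, B and C. Those with TAOK2 siRNA held 10.6, 12.5 and 8.56 TPM. DMSO libraries held 39.7, 40.6 and 37.5 TPM and compound 2 libraries 21.5, 30.7 and 20.5 TPM. In the fractionation experiment, batches 1 and 2 held 9.70 and 5.01 TPM in control total RNA and 3.67 and 2.99 after knockdown. Nuclear RNA held 15.6 and 9.31 TPM with control siRNA and 9.68 and 6.24 with TAOK2 siRNA. Cytoplasmic RNA held 7.63 and 3.37 and 2.41 and 0.728 TPM. The paralogs TAOK1 (log2 change 0.01, adjusted p = 0.980) and TAOK3 (0.14, 0.391) did not pass the limma test under knockdown.

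**Figure D1:**
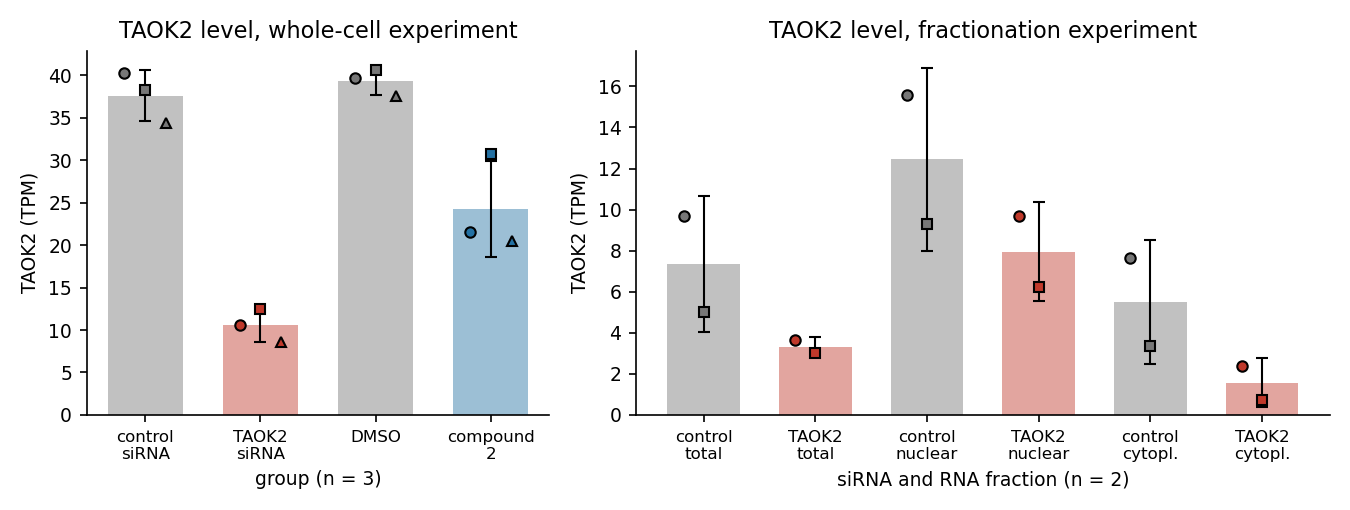
TAOK2 level in TPM (vertical axis) in each library, by group on the horizontal axis; bars are group means, error bars the SD, and circles, squares and triangles the batches. Whole cells held 10.6 TPM on average after knockdown and 37.6 TPM with control siRNA.

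The whole-cell knockdown comparison asked which RNAs change with siRNA against TAOK2. Knockdown lowered TAOK2 itself (-1.75 ± 0.15, adjusted p = 2.32e-05 by limma, log2 change ± SE). Its level was 10.6 ± 1.98 against 37.6 ± 3.03 TPM (SD, n = 3). STC1, a secreted glycoprotein hormone, rose most among genes with a mean of at least 5 TPM (2.16 ± 0.42, adjusted p = 0.00531), to 35.7 ± 8.36 against 7.24 ± 2.10 TPM. The epithelial membrane protein gene EMP1 (1.62 ± 0.20, adjusted p = 0.000329) and LAMB3, a laminin chain of the basement membrane (1.46 ± 0.12, adjusted p = 1.44e-05), also rose. RAB1B, a small GTPase of transport from the endoplasmic reticulum to the Golgi, fell most (-2.29 ± 0.08, adjusted p = 1.25e-08), to 39.9 ± 2.15 against 199.6 ± 14.5 TPM. The coiled-coil gene CCDC43 (-2.04 ± 0.08, adjusted p = 5.31e-08), the Wnt signal enhancer RSPO3 (-1.89 ± 0.16, adjusted p = 2.09e-05) and the heme oxygenase HMOX1 (-1.66 ± 0.17, adjusted p = 7.24e-05) fell too. RAB1B and CCDC43 fell further than TAOK2 itself, and off-target effects of the siRNA pool were not tested.

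Of 13106 genes tested with limma, 2905 passed at an adjusted p of 0.05, 1020 higher and 1885 lower. Of these, 113 changed at least 2-fold (52 up, 61 down). The other genes among the 10 largest rises were the matrix glycoprotein EFEMP1, the thrombin receptor THBD, PPP1R3C, C1orf116, the collagen chain COL12A1, the protease inhibitor TFPI2 and the mucin MUC3A. Their log2 changes ran from 1.25 to 1.79. Further large falls were in FXYD2, a regulator of the sodium pump, the splicing regulator RBFOX3, RFLNB and OLFML3, with changes from -2.27 to -1.61. All of these changed in the same direction in all 3 batches. FXYD2, OLFML3 and RBFOX3 lost their calls without control siRNA replicate 1 or 2 or TAOK2 siRNA replicate 2 or 3 (adjusted p up to 0.141, 0.0874 and 0.0701). FXYD2 also did with no filter on low values (0.0639) and with median-centred values (0.0508). The number of calls was 1678 without TAOK2 siRNA replicate 2, 1830 without control siRNA replicate 1 and 1852 without control siRNA replicate 2. With median-centred values, 2812 passed, 1269 higher and 1543 lower.

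Lists of cell division genes were called lower under knockdown. Among G2/M genes, 0 rose and 20 fell of 41 measured (0 and 29 adjusted over the list alone). The cyclins CCNA2 and CCNB1, the kinesin KIF2C and the survivin gene BIRC5 were among them (CCNA2 -0.97, CCNB1 -0.43, KIF2C -0.69 and BIRC5 -0.46). By camera the list had adjusted p = 1.7e-08, and 0.554 with an estimated correlation. Among DNA replication genes, 1 rose and 20 fell of 46 measured (1 and 27 adjusted over the list alone) (adjusted p = 1.8e-05, and 0.554 with an estimated correlation). GINS2 and MCM2 of the replicative helicase and the cyclin gene CCNE1 fell (GINS2 -1.14, MCM2 -0.48 and CCNE1 -1.27). Cytosolic ribosomal protein genes moved up by a median of 0.16 (adjusted p = 3.07e-11, and 0.554 with an estimated correlation). Of these, 21 rose and 1 fell of 73 measured (31 and 1 adjusted over the list alone), with RPS3, RPS6 and RPL13A among the former (RPS3 0.30, RPS6 0.33 and RPL13A 0.29). With batch as a block 38 ribosomal protein genes rose and 1 fell.

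Several lists of RNA processing genes were called lower after knockdown by camera with its preset correlation, and 0 with an estimated correlation. For scale, 1885 of all 13106 genes tested were lower. Of 10 splits of these libraries, the real one included, 4 gave at least the real 15 list calls. In the core spliceosome, 0 rose and 15 fell of 53 measured (0 and 16 adjusted over the list alone). SNRPA1 and SNRNP70 of the U2 and U1 particles and the splice site factor U2AF2 were lower (SNRPA1 -0.56, SNRNP70 -0.45 and U2AF2 -0.39), and the list had adjusted p = 7.06e-05, and 0.380 with an estimated correlation. For nuclear RNA decay, 0 rose and 11 fell of 22 measured (0 and 11 adjusted over the list alone) (adjusted p = 0.000537, and 0.554 with an estimated correlation). The exosome nuclease DIS3 (-1.26 ± 0.11, adjusted p = 2.65e-05), its cofactor C1D and the core subunit EXOSC5 were lower (C1D -0.94 and EXOSC5 -0.66). For mRNA export and the exon junction complex, 1 rose and 11 fell of 36 measured (1 and 15 adjusted over the list alone). The adaptor ALYREF, the helicase DDX39A and CASC3 fell (ALYREF -0.36, DDX39A -0.77 and CASC3 -0.69), and the list had adjusted p = 0.00111, and 0.554 with an estimated correlation. Among hnRNP proteins and splicing regulators, 1 rose and 11 fell of 41 measured (1 and 15 adjusted over the list alone, and 1 and 18 over all genes with batch as a block), at adjusted p = 0.00427, and 0.613 with an estimated correlation. MATR3, KHDRBS1 and HNRNPH2 fell (MATR3 -0.63, KHDRBS1 -0.47 and HNRNPH2 -0.43). Cleavage and polyadenylation factors were called lower, with 0 up and 4 down of 24 (0 and 4 adjusted over the list alone) at adjusted p = 0.0294, and 0.554 with an estimated correlation. CSTF2 and CPSF2 were among them (CSTF2 -0.69 and CPSF2 -0.40). Nonsense-mediated decay factors were called lower as well, with 0 up and 5 down of 16 (0 and 5 adjusted over the list alone) at adjusted p = 0.0305, and 0.613 with an estimated correlation (DHX34 -0.43 and UPF2 -0.41). The speckle scaffold and SR protein list, with 0 up and 6 down of 33 (0 and 5 adjusted over the list alone), was not called (adjusted p = 0.231, and 0.815 with an estimated correlation). Of its members, SREK1, SRSF4 and SRSF1 fell (SREK1 -0.51, SRSF4 -0.54 and SRSF1 -0.28). In the list of SR protein kinases and phosphatases, 1 rose and 2 fell of 20 measured (1 and 2 adjusted over the list alone) (adjusted p = 0.882, and 0.952 with an estimated correlation). SRPK2 and PPP1R8 fell and SRPK1 rose (SRPK2 -1.03, PPP1R8 -0.85 and SRPK1 0.34).

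Stress and signalling groups moved in both directions. In the amino acid and integrated stress response, 1 rose and 14 fell of 39 measured (2 and 16 adjusted over the list alone), at adjusted p = 0.00141, and 0.613 with an estimated correlation. The cysteine synthesis enzyme CBS, the tRNA synthetases AARS1 and NARS1 and the transcription factor CEBPB fell (CBS -0.71, AARS1 -0.54, NARS1 -0.43 and CEBPB -0.60). Interferon-stimulated genes were called up, with 7 up and 1 down of 30 (8 and 1 adjusted over the list alone) at adjusted p = 0.00100, and 0.380 with an estimated correlation. OAS1, SAMD9 and IFIT2 rose (OAS1 1.23, SAMD9 1.22 and IFIT2 0.68). Immediate early genes were called up too, with 5 up and 1 down of 32 (5 and 1 adjusted over the list alone) at adjusted p = 0.00786, and 0.613 with an estimated correlation. The nuclear receptors NR4A1 and NR4A2, KLF2 and the phosphatase DUSP5 rose (NR4A1 0.55, NR4A2 1.08, KLF2 1.18 and DUSP5 0.89). Among epithelial and mesenchymal state genes, with 3 up and 0 down of 22 (2 and 0 adjusted over the list alone, 5 and 1 over all genes with the block), keratin KRT19, vimentin and N-cadherin rose (KRT19 1.16, VIM 0.50 and CDH2 0.72). That list had adjusted p = 0.0122, and 0.380 with an estimated correlation. Among kinases acting with TAOK2, the stress kinase MAPK14 and its activator MAP2K4 fell and MAP3K5 rose (MAPK14 -0.54, MAP2K4 -0.91 and MAP3K5 0.54). The list of TAO kinases and their cascades, with 1 up and 4 down of 27 (1 and 3 adjusted over the list alone), or 5 up and 4 down with the block, was not called (adjusted p = 0.487, and 0.905 with an estimated correlation). Cholesterol synthesis genes, with 5 up and 3 down of 25 (5 and 3 adjusted over the list alone), missed the threshold (adjusted p = 0.0515, and 0.682 with an estimated correlation). That list with batch as a block had an adjusted p of 0.0471, and 0.696 with an estimated correlation as well.

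Camera with its preset correlation called 15 of 35 lists under knockdown, 6 up and 9 down, and 0 with an estimated correlation, and fry called 16. Mitochondrially encoded messenger RNAs were called higher, with 1 up and 0 down of 13 (1 and 0 adjusted over the list alone) at adjusted p = 0.0305, and 0.613 with an estimated correlation. Endoplasmic reticulum and secreted protein genes were too, with 5 up and 1 down of 30 (5 and 1 adjusted over the list alone) at adjusted p = 0.0419, and 0.380 with an estimated correlation. YAP and TEAD targets, with 2 up and 2 down of 27 (0 and 1 adjusted over the list alone, 4 and 3 over all genes with the block), were not called. The lists of p53 targets, with 1 up and 5 down of 29 (2 and 5 adjusted over the list alone), and NF-kB genes, with 0 up and 5 down of 25 (0 and 5 adjusted over the list alone), were not called either. NRF2 targets, with 4 up and 6 down of 32 (4 and 7 adjusted over the list alone), were not called although the ferritin genes FTL and FTH1 fell (FTL -1.16 and FTH1 -0.37). Hypoxia and glycolysis genes, with 3 up and 9 down of 31 (4 and 9 adjusted over the list alone), were not called, and ADM and PFKFB3 fell (ADM -1.10 and PFKFB3 -1.19).

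The inhibitor comparison asked which RNAs change with compound 2, which the labels give as an inhibitor of TAOK2 kinase activity. That activity was not measured here. Compound 2 lowered the stress response transcription factor DDIT3 (-3.24 ± 0.19, adjusted p = 6.32e-08), to 13.9 ± 5.32 against 135 ± 21.5 TPM (SD, n = 3). GTPBP2, a GTPase that helps rescue stalled ribosomes, fell (-3.09 ± 0.10, adjusted p = 8.4e-10), and FAM83G fell most (-3.38 ± 0.14, adjusted p = 2.28e-09). EID3, which binds a histone acetyltransferase, rose most (5.37 ± 0.19, adjusted p = 1.72e-09), to 419 ± 46.7 against 9.20 ± 1.78 TPM. KANSL1, a subunit of a histone acetyltransferase complex, rose (2.66 ± 0.11, adjusted p = 1.95e-09). TAOK2 RNA was lower under the compound (-0.70 ± 0.15, adjusted p = 0.00136) and TAOK3 fell (-0.92 ± 0.11, adjusted p = 1.25e-05). TAOK1 was -0.36 (adjusted p = 0.0126), with a sign that differed between batches.

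Most tested genes passed: 8354 of 13106, 1571 higher and 6783 lower. Of these, 2393 changed at least 2-fold (172 up, 2221 down). TPM is a share of a fixed total, and the median gene changed by -0.31. With median-centred values 8345 passed, 4262 higher and 4083 lower, so the direction of a small change is relative to that median. Other large falls were in the tensin TNS4, ZC3H4, which limits transcription of noncoding RNA, ZSWIM4, KRCC1, SLFN5, the mitotic kinesin KIF18B and the death receptor adaptor FADD. They ran from -3.24 to -2.95. Other large rises were in the pseudogenes CHMP4BP1, DNAJC8P2, SLC7A5P1, RPL4P6, UBE2FP1 and RNA5-8SP6, in ANKRD30BL and in the readthrough gene RNF103-CHMP3. These ran from 2.48 to 4.93. Pseudogenes share sequence with their parents, and the share of TPM assigned to each copy is uncertain. Of the 172 genes that rose at least 2-fold, 62 were pseudogenes, against 650 of 13106 tested (odds ratio 11.8, 95% interval 8.43 to 16.5).

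Amino acid and integrated stress response genes fell as a group under compound 2, by a median of -0.96. Here 1 rose and 34 fell of 39 measured (1 and 34 adjusted over the list alone), at adjusted p = 0.000156, and 0.735 with an estimated correlation. The mitochondrial gluconeogenic enzyme PCK2, CBS, AARS1 and MARS1 fell (PCK2 -2.19, CBS -1.88, AARS1 -1.55 and MARS1 -1.34). G2/M genes fell too, with 3 up and 32 down of 41 (3 and 33 adjusted over the list alone) at adjusted p = 0.00246, and 0.838 with an estimated correlation. The spindle genes ASPM, KIF11 and KIF2C and the phosphatase CDC25C were lower (ASPM -2.43, KIF11 -1.61, KIF2C -1.87 and CDC25C -1.80). KRAB zinc finger genes, a family of transcriptional repressors, fell with 6 up and 50 down of 66 (6 and 50 adjusted over the list alone) at adjusted p = 0.0154, and 0.838 with an estimated correlation, for example ZNF189 -2.62, ZNF45 -2.29 and ZNF324 -2.44. Cytosolic ribosomal protein genes rose, with 60 up and 0 down of 73 (63 and 0 adjusted over the list alone) at adjusted p = 1.39e-23, and 0.467 with an estimated correlation. RPL5 and RPL18 were among them (RPL5 0.38 and RPL18 0.37). Nuclear-encoded respiratory chain genes rose, with 44 up and 3 down of 70 (44 and 3 adjusted over the list alone) at adjusted p = 1.13e-17, and 0.196 with an estimated correlation, for example NDUFC2 0.53 and ATP5MG 0.44. Heat shock proteins were called up, with 9 up and 3 down of 23 (9 and 3 adjusted over the list alone) at adjusted p = 6.67e-05, and 0.196 with an estimated correlation. HSPE1, HSP90AA1 and HSP90AB1 were among the genes that rose (HSPE1 0.41, HSP90AA1 0.43 and HSP90AB1 0.48). Mitochondrially encoded messenger RNAs were called up, with 6 up and 0 down of 13 (3 and 0 adjusted over the list alone) at adjusted p = 0.000167, and 0.559 with an estimated correlation. Immediate early genes were called up, with 12 up and 10 down of 32 (12 and 10 adjusted over the list alone) at adjusted p = 0.000592, and 0.559 with an estimated correlation. FOS and IER5 rose and ZFP36 fell (FOS 1.99, IER5 1.22 and ZFP36 -0.80).

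RNA processing genes split under compound 2. In the speckle scaffold and SR protein list, 15 rose and 9 fell of 33 measured (15 and 10 adjusted over the list alone), at adjusted p = 0.000195, and 0.559 with an estimated correlation. LUC7L3 and SCAF4 rose, and SRSF3 and THRAP3 fell (LUC7L3 1.33, SCAF4 0.90, SRSF3 -1.46 and THRAP3 -1.46). The splicing and transcription kinases CDK12, DYRK1B and CLK2 fell (CDK12 -2.07, DYRK1B -1.69 and CLK2 -1.33), as did the decay factor SMG9, while the kinase SMG1 rose (SMG9 -2.71 and SMG1 1.12). The exosome adaptor ZC3H18 and subunit EXOSC3 fell (ZC3H18 -2.25 and EXOSC3 -1.55). The polyadenylation factors CSTF2T and CPSF7 fell and RBBP6 rose (CSTF2T -2.11, CPSF7 -1.56 and RBBP6 1.47). Core spliceosome genes were not called as a list, with 12 up and 23 down of 53 (13 and 23 adjusted over the list alone) at adjusted p = 0.142, and 0.838 with an estimated correlation. Nor were mRNA export genes, with 5 up and 20 down of 36 (5 and 20 adjusted over the list alone) at adjusted p = 0.946, and 0.989 with an estimated correlation, or DNA replication genes, with 2 up and 28 down of 46 (3 and 28 adjusted over the list alone) at adjusted p = 0.411, and 0.909 with an estimated correlation.

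Camera called 16 of 35 lists under compound 2, 13 up and 3 down, 0 with an estimated correlation, and fry called 26. Of the camera calls, 7 were called up although their median or mean change was below 0, since camera compares a list with all other genes. Genes with known detained introns or poison exons, with 12 up and 7 down of 27 (12 and 8 adjusted over the list alone), had a median of -0.04 and a mean of 0.15 (adjusted p = 0.000592). The others, each with its median, mean and camera adjusted p, were hypoxia genes (-0.00208 and -0.06, adjusted p = 0.00394), unfolded protein response genes (0.08 and -0.10, adjusted p = 0.0226), hnRNP proteins (0.05 and -0.12, adjusted p = 0.0274), histones (0.05 and -0.08, adjusted p = 0.0387), NRF2 targets (-0.01 and -0.18, adjusted p = 0.0387) and microtubule genes (-0.02 and -0.11, adjusted p = 0.0414). With an estimated correlation their adjusted p ran from 0.196 to 0.838. The interferon list, with 0 up and 16 down of 30 (0 and 16 adjusted over the list alone), was not called (adjusted p = 0.955). STAT2 and IRF9 of that list fell (STAT2 -1.51 and IRF9 -1.54).

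**Figure D2:**
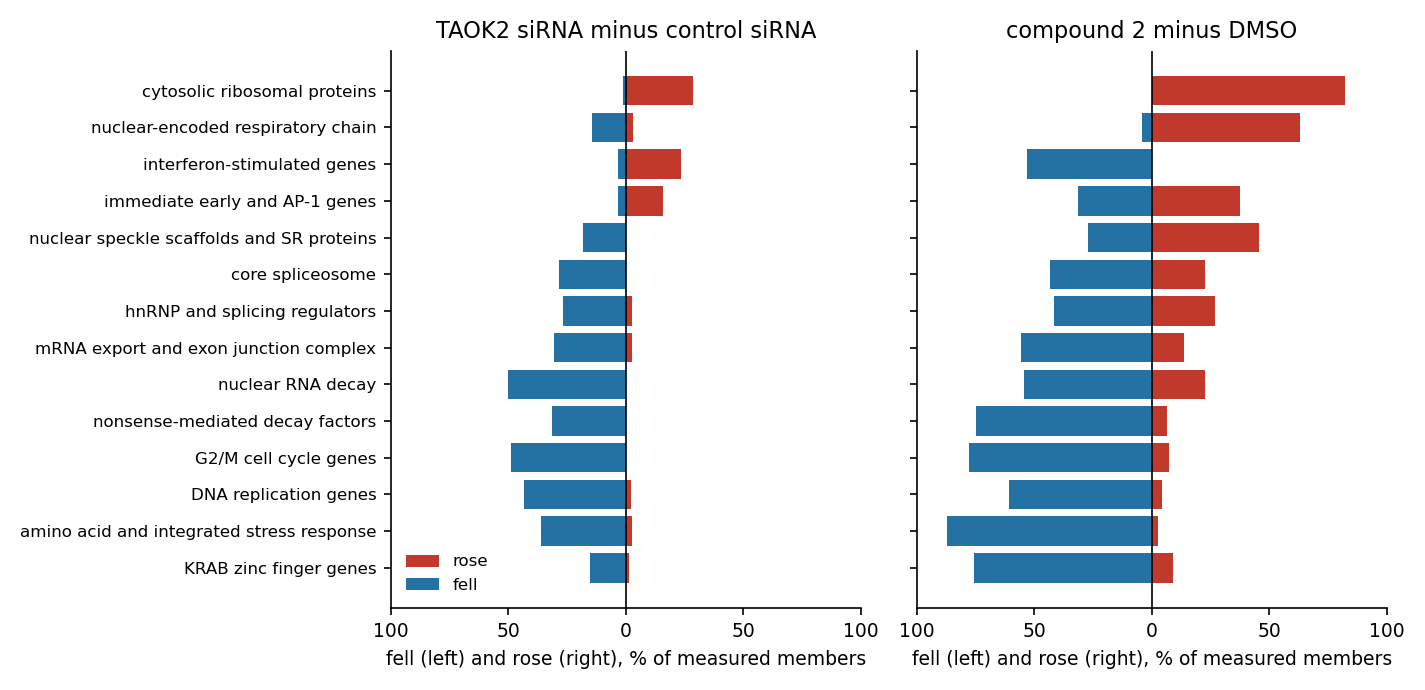
Percent of measured genes (horizontal axis) that rose or fell at an adjusted p of 0.05 in 14 gene lists (vertical axis), for TAOK2 knockdown and compound 2 in whole cells, with bars to the right for genes that rose and to the left for those that fell. Amino acid and integrated stress response genes had 34 of 39 lower with compound 2 and 14 lower with knockdown.

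Setting both perturbations side by side asked whether loss of the RNA and the compound change the same genes. PPP1R3C, C1orf116 and the tensin TNS4 were higher with knockdown than with compound 2, each set against its own control. The differences of log2 changes were 3.4 ± 0.47, 3.90 ± 0.27 and 4.0 ± 0.21, with adjusted p = 0.000113, 4.51e-07 and 9.82e-08 by limma. EID3 (-5.20 ± 0.27), KANSL1 (-2.57 ± 0.15) and CYP1B1, a xenobiotic oxidase (-2.55 ± 0.49), were lower. TAOK2 differed by -1.06 ± 0.21, adjusted p = 0.00114, and TAOK3 by 1.06 ± 0.16, adjusted p = 0.000120. Integrated stress response genes fell less with knockdown. In that list 27 differed upwards and 1 downwards of 39 (27 and 1 adjusted over the list alone). PCK2, ALDH1L2 and CARS1 were among them (PCK2 1.78, ALDH1L2 1.82 and CARS1 1.65), and the list had adjusted p = 0.00348, and 0.781 with an estimated correlation. Respiratory chain genes differed downwards, with 0 up and 41 down of 70 (0 and 41 adjusted over the list alone) at adjusted p = 2.72e-15, and 0.207 with an estimated correlation. Speckle scaffold and SR protein genes did too, with 6 up and 15 down of 33 (6 and 16 adjusted over the list alone) at adjusted p = 0.000306, and 0.781 with an estimated correlation.

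In all, 7174 of 13106 genes differed between the responses, 5560 upwards and 1614 downwards by limma (3550 and 3554 with median-centred values). Across genes, which are not independent replicates, the changes correlated at r = 0.0576 (Spearman 0.0667), and at 0.0511, 0.0526 and 0.0271 within batches A, B and C. Genes called up in both numbered 131, where independent lists give 122, and those called down in both 1041, where they give 976. Genes up with knockdown and down with compound 2 numbered 478 (528 for independent lists), and the reverse 248 (226). Camera called 10 lists, 1 up and 9 down (0 with an estimated correlation), and fry 13. Core spliceosome genes, with a median of -0.10 and a mean of 0.05, and NRF2 targets, with -0.04 and 0.01, were called down. The list of unfolded protein response genes moved from an adjusted p of 0.0502 to 0.0407 with batch as a block (0.822 with an estimated correlation as well).

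Control siRNA was compared with DMSO to show what separates the references of both perturbations. The prostaglandin synthase PTGS2 (2.16 ± 0.53, adjusted p = 0.0433) was higher with control siRNA, at 165 ± 15.2 against 41.4 ± 24.8 TPM (SD, n = 3). The nuclear receptor NR4A1 (1.41 ± 0.11, adjusted p = 0.000112) and GASK1B (1.69 ± 0.24, adjusted p = 0.00355) were higher too. MUC3A (-1.23 ± 0.15, adjusted p = 0.00175), SYNE1 (-1.16) and the growth factor receptor EGFR (-0.90) were lower. TAOK2 did not pass (-0.06, adjusted p = 0.859). Cholesterol synthesis genes were higher as a group, with 11 up and 1 down of 25 (17 and 1 adjusted over the list alone) at adjusted p = 7.63e-09, and 0.315 with an estimated correlation. INSIG1, SREBF2 and DHCR7 were among them (INSIG1 1.09, SREBF2 0.62 and DHCR7 0.65). Unfolded protein response genes were higher, with 11 up and 0 down of 25 (15 and 0 adjusted over the list alone) at adjusted p = 4.03e-09, and 0.315 with an estimated correlation, for example HSPA5 0.48, MANF 0.50 and DNAJB9 0.68. G2/M genes were lower, with 0 up and 13 down of 41 (0 and 26 adjusted over the list alone, 0 and 20 over all genes with the block) at adjusted p = 5.44e-17, and 0.315 with an estimated correlation. Hypoxia genes were called up, with 7 up and 1 down of 31 (8 and 2 adjusted over the list alone) at adjusted p = 0.0314, and 0.315 with an estimated correlation, but not with batch as a block (adjusted p = 0.0672).

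By limma 843 of 13106 genes passed, 566 higher and 277 lower, 66 at least 2-fold. The block by batch passed 1543. The count was 165 without control siRNA replicate 1, 117 without control siRNA replicate 2, and 487, 366 and 389 without DMSO replicates 1, 2 and 3. NR4A1, GASK1B and MUC3A kept their calls in each. PTGS2 (up to 0.148), SYNE1 (0.133) and EGFR (0.115) lost theirs without control siRNA replicate 1 or 2 and in part without others. With no filter on low values PTGS2 (0.0696), SYNE1 (0.0619) and EGFR (0.0588) lost them too, and PTGS2 also did median-centred (0.0515) and with only the compared groups in the fit (0.0725). Camera called 18 lists, 8 up and 10 down (0 with an estimated correlation), and fry 6. With batch as a block, endoplasmic reticulum and secreted protein genes moved from 0.0582 to 0.0286 and alveolar and airway identity genes from 0.0672 to 0.0218 (0.551 and 0.299 with an estimated correlation as well).

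Transcript usage, the share of a gene's TPM held by each of its transcripts, addressed RNA processing itself. Under knockdown, the main transcript of MORN2 (ENST00000340556) held 53.6 ± 9.67% against 95.1 ± 1.46% of its gene (SD, n = 3), with an adjusted p of 0.00189 by limma. The coding transcript of NHLRC2, a thioredoxin domain protein, held 95.3 ± 1.18% against 76.8 ± 8.02%, and its retained-intron transcript 4.65 ± 1.18% against 23.2 ± 8.02% (adjusted p = 0.0442 for each). The shares of IGF2BP1, an RNA-binding protein (69.2 ± 1.28% against 49.6 ± 4.78%), the tropomyosin TPM2 (64.8 ± 1.12% against 47.8 ± 0.0821%), RCC1 (22.5 ± 0.660% against 13.9 ± 1.03%) and NECTIN2 (50.9 ± 0.342% against 37.9 ± 1.52%) rose for the transcripts named by the rule. Those of CDS2 (1.5 ± 1.24% against 8.56 ± 1.18%), FNDC3B (1.5 ± 0.606% against 6.50 ± 1.39%) and WNT7B (96.8 ± 0.762% against 98.9 ± 0.431%) fell. By limma 36 of 41006 transcripts passed, in 28 of 9986 genes (20 higher, 16 lower). Leaving out a library left 13, 12 and 10 without control siRNA replicates 1, 2 and 3. It left 10, 11 and 10 without TAOK2 siRNA replicates 1, 2 and 3.

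Compound 2 changed the usage of 14224 of 41006 transcripts in 6236 genes, 6806 higher and 7418 lower by limma. A retained-intron transcript of MTCL1, a microtubule crosslinking factor, held 52.1 ± 3.27% against 0.298 ± 0.127% of its gene (adjusted p = 9.97e-08). Transcripts of 541 nt of the ribosome biogenesis gene WDR43 (35.2 ± 4.17% against 0.319 ± 0.289%) and 596 nt of the cytokinesis gene ANLN (28.6 ± 5.87% against 0.0644 ± 0.112%) gained share. A WNT7B transcript of 2285 nt (36.1 ± 0.582% against 0.521 ± 0.276%) gained share too. A transcript of thioredoxin reductase TXNRD1 (ENST00000503506) that held 27.0% in DMSO was at 6.97e-08% with compound 2. ENST00000526266 of that gene held 9.41 ± 0.492% against 0.0636 ± 0.00946%. Transcripts of SRGAP1 (9.20 ± 5.98% against 92.0 ± 0.150%), LENG8 (3.33 ± 5.36% against 50.4 ± 4.71%), PTP4A2 (0.00642 ± 0.0111% against 14.4 ± 4.43%) and a nonsense-mediated decay transcript of the helicase gene DDX3X (0.327 ± 0.236% against 22.2 ± 2.19%) lost share. Of 5972 retained-intron transcripts, 1092 gained and 1413 lost share. Of 3571 nonsense-mediated decay transcripts, 553 gained and 465 lost, and of 4903 processed transcripts, 1226 gained and 725 lost.

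Nuclear and cytoplasmic RNA of control cells were compared to see how the fractions part. The fraction marker MT-CO1, encoded in mitochondria, was higher in the nuclear fraction (2.88 ± 0.17, adjusted p = 1.4e-05), while GAPDH was lower (-1.12 ± 0.14, adjusted p = 0.000335) and ACTB was -0.83 (adjusted p = 0.0535, and 3.77e-05 with batch as a block). AHSA2P (5.32 ± 0.44, adjusted p = 4.56e-05) was the most nuclear, at 301 ± 34.9 against 6.55 ± 1.18 TPM (SD, n = 2). BRCA1P1, PABPC1L, the golgin GOLGA8A and SLC25A27 followed, with log2 ratios down to 5.07. The ribosomal protein genes RPS29, RPL37A and RPL39, the actin-binding thymosin TMSB10 and ferritin FTL were the most cytoplasmic, from -3.20 to -2.90. RPS29 lost its call without control nuclear replicate 2 or control cytoplasmic replicate 1 (adjusted p up to 0.0842), and kept it without each library with batch as a block (up to 9.65e-06). Ribosomal protein genes as a group were cytoplasmic, with 67 of 73 lower in nuclei (68 adjusted over the list alone), at adjusted p = 6.8e-26, and 0.0199 with an estimated correlation. Respiratory chain genes were too, with 50 of 71 (53 adjusted over the list alone), at adjusted p = 1.68e-13, and 0.00313 with an estimated correlation. The same lists with the block by batch had adjusted p = 0.128 and 0.0553 with an estimated correlation. Detained-intron genes were nuclear, with 22 of 27 higher in nuclei (23 adjusted over the list alone), at adjusted p = 5.54e-06, and 0.632 with an estimated correlation. Speckle and SR protein genes were nuclear, with 26 of 33 (26 adjusted over the list alone), at adjusted p = 1.23e-05, and 0.632 with an estimated correlation. KRAB zinc finger genes were nuclear, with 35 of 62 (37 adjusted over the list alone), at adjusted p = 2.75e-05, and 0.733 with an estimated correlation. OGT, ACIN1, SRSF11, RBM39 and ZNF224 were examples of these groups (OGT 4.08, ACIN1 3.73, SRSF11 3.16, RBM39 2.81 and ZNF224 4.08).

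By limma 6699 of 13751 genes differed between the fractions, 4101 nuclear and 2598 cytoplasmic (3362 and 3411 with median-centred values, 7251 and 1248 rescaled without mitochondrial genes), 4689 at least 2-fold. The median gene stood at 0.21, and at 0.80 once TPM was rescaled without mitochondrial genes, which held 36.5% to 42.5% of nuclear TPM and 8.10% to 13.9% of cytoplasmic TPM. TAOK2 RNA had a nuclear to cytoplasmic log2 ratio of 1.09 ± 0.47 (adjusted p = 0.0873, and 0.000895 with batch as a block). Nonsense-mediated decay factors were called with the block alone (adjusted p = 0.0807, then 0.0413), and not with an estimated correlation (0.449, then 0.474).

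Knockdown in the fractionation experiment asked where in the cell the changes appear. LUM, a matrix proteoglycan (1.75 ± 0.15, adjusted p = 0.0166), rose in nuclear RNA by limma, to 24.4 ± 0.733 against 6.56 ± 0.431 TPM (SD, n = 2). ACAT2, an enzyme of cholesterol synthesis (1.63 ± 0.15, adjusted p = 0.0166), rose there too, to 27.0 ± 0.531 against 8.03 ± 0.213 TPM. STC1 was the strongest in total RNA (1.47 ± 0.17, adjusted p = 0.0524) and cytoplasmic RNA (1.51 ± 0.17, adjusted p = 0.0642) and did not pass. TAOK2 did not pass in total (-0.89 ± 0.47, adjusted p = 0.880), nuclear (-0.57 ± 0.47, 0.834) or cytoplasmic RNA (-1.34 ± 0.47, 0.565). With batch as a block its adjusted p was 0.0522, 0.121 and 0.0128. Limma passed 0 of 13751 genes in total, 2 in nuclear and 0 in cytoplasmic RNA. At an unadjusted p of 0.05 the counts were 917, 1328 and 933. With batch as a block it passed 339 in total RNA (228 higher, 111 lower, or 300 and 194 median-centred). In nuclear RNA it passed 811 (381 and 430, 575 and 487 median-centred, or 432 and 878 rescaled without mitochondrial genes). In cytoplasmic RNA it passed 404 (205 and 199, 363 and 208 median-centred, or 190 and 276 rescaled). Leaving out a library as well moved these far: to 0, 0, 276 and 18 in total, 13, 20, 23 and 18 in nuclear and 362, 1464, 26 and 7 in cytoplasmic RNA (without TAOK2 siRNA replicates 1 and 2, then control siRNA replicates 1 and 2). Without the block, the calls of LUM and ACAT2 were lost without any 1 of the 4 nuclear libraries (adjusted p up to 0.324). With it both held without each (up to 0.0438 and 0.0472).

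With batch as a block, EMP1 and the secreted growth factor carrier FGFBP1 rose in total (EMP1 1.60 and FGFBP1 1.56), nuclear (EMP1 1.92 and FGFBP1 1.73) and cytoplasmic RNA (EMP1 1.76 and FGFBP1 1.98), and BEX2 fell in each (-2.25, -1.59 and -1.88). TRIM29 and STC1 rose in total RNA (TRIM29 1.81 and STC1 1.47), and the chaperone CLGN and the serine synthesis enzyme PHGDH fell (CLGN -1.34 and PHGDH -1.31). The thymidine kinase TK1 rose in nuclear and cytoplasmic RNA (1.85 and 1.44), the chemokine CXCL8 in cytoplasmic RNA (1.49), and in nuclear RNA TMEM178A and PABPC1L fell (TMEM178A -1.60 and PABPC1L -1.38). Pseudogenes filled the largest cytoplasmic falls (TAF9P3 -2.44, FTH1P15 -2.26 and RDM1P4 -2.17), where reads shared with parents leave the assignment uncertain. In nuclear and cytoplasmic RNA, the blocked calls of EMP1 and FGFBP1 held without each library (adjusted p up to 0.0491). In total RNA every blocked call, theirs included, was lost without TAOK2 siRNA total replicate 1 or 2 (EMP1 0.0812 and 0.0622). The other calls named here were lost without at least 1 library.

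Cholesterol synthesis genes moved up after knockdown in every fraction, by medians of 0.71 in total, 0.71 in nuclear and 0.65 in cytoplasmic RNA. Of 25 genes in total RNA, 10 up and 0 down adjusted over the list alone, 15 and 0 over all genes with the block, among them EBP, SQLE and FDPS (EBP 0.91, SQLE 0.88 and FDPS 0.71). These calls held with an estimated correlation (adjusted p = 0.00347, 0.00254 and 0.00229). With the block those values were 0.0423, 0.0387 and 0.0348. G2/M genes moved up by 0.73, 0.72 and 0.58. Of 41 in total RNA, 9 up and 0 down adjusted over the list alone, 22 and 0 over all genes with the block, among them MKI67, PLK1 and AURKA (MKI67 1.40, PLK1 1.03 and AURKA 0.74). Their adjusted p was 2.06e-21, 2.74e-21 and 2.84e-20, and 0.262, 0.185 and 0.201 with an estimated correlation. DNA replication genes moved up by 0.59, 0.49 and 0.46, with 9, 4 and 2 of 45 higher adjusted over the list alone (28, 24 and 20 with the block). For these the adjusted p was 1.44e-17, 7.2e-17 and 2.59e-17, and 0.0606, 0.0444 and 0.0638 with an estimated correlation, the nuclear value being 0.0900 with the block. RRM2 and CDC6 rose in total RNA with the block (RRM2 1.36 and CDC6 1.07).

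Integrated stress response genes moved down in each fraction, by -0.61 in total, -0.44 in nuclear and -0.74 in cytoplasmic RNA. Of 39 in total RNA, 0 up and 16 down adjusted over the list alone, 0 and 12 over all genes with the block, among them DDIT3, ASNS and PSAT1 (DDIT3 -1.39, ASNS -1.27 and PSAT1 -0.92). The adjusted p was 1.49e-20, 2.18e-09 and 1.11e-19, and 0.112, 0.268 and 0.147 with an estimated correlation. Interferon-stimulated genes moved up by 0.43, 0.39 and 0.34, with 9, 8 and 4 of 36 higher adjusted over the list alone (15, 13 and 9 with the block). Their adjusted p was 2.55e-11, 6.11e-10 and 1e-07, and 0.0408, 0.0358 and 0.0638 with an estimated correlation. With the block the latter were 0.0556, 0.0601 and 0.0859. IFI44 and OAS1 rose in total RNA with the block (IFI44 1.42 and OAS1 1.29). The genes named in total RNA for these and the cholesterol and cell division lists lost their blocked calls without TAOK2 siRNA total replicate 1 or 2.

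In nuclear RNA, detained-intron genes moved down by a median of -0.29 (adjusted p = 0.000443, and 0.559 with an estimated correlation). Of 27 such genes, 0 up and 1 down adjusted over the list alone, 0 and 8 over all genes with the block, among them OGT, ARGLU1 and MAT2A (OGT -1.19, ARGLU1 -0.73 and MAT2A -0.58). Speckle and SR protein genes moved down by -0.24 (adjusted p = 0.00602, and 0.580 with an estimated correlation). Of 33 of these, 0 up and 0 down adjusted over the list alone, 0 and 8 over all genes with the block, with RBM39 and LUC7L3 lower with the block (RBM39 -0.57 and LUC7L3 -0.69). Hypoxia and glycolysis genes moved up by 0.50 (adjusted p = 6.11e-10, and 0.0358 with an estimated correlation, or 0.211 with the block). Of 31, 8 up and 1 down adjusted over the list alone, 12 and 1 over all genes with the block, including GAPDH, PGAM1 and PKM (GAPDH 0.77, PGAM1 0.74 and PKM 0.82). The blocked nuclear calls of OGT, ARGLU1, MAT2A, RBM39, LUC7L3, GAPDH, PGAM1 and PKM were each lost without any 1 of the 4 nuclear libraries. Respiratory chain genes moved up by 0.26 (adjusted p = 1.58e-08, and 0.00695 with an estimated correlation, or 0.0601 with the block). Cytosolic ribosomal protein genes, the most cytoplasmic list in control cells (median -2.25), moved up by 0.23 as well (adjusted p = 1.27e-06, and 0.132 with an estimated correlation). Camera called 13, 16 and 13 of 36 lists in total, nuclear and cytoplasmic RNA, and 2, 7 and 2 with an estimated correlation, and fry called 6, 7 and 5. Block values crossed the threshold for mitochondrially encoded messenger RNAs (0.0701 to 0.00941, and 0.766 with an estimated correlation as well) and fibroblast and endothelial markers (0.0238 to 0.0748) in total RNA. In nuclear RNA they did so for YAP targets (0.0282 to 0.0697), unfolded protein response (0.0807 to 0.0496), secreted protein (0.0991 to 0.0398) and alveolar genes (0.0768 to 0.0490), the last 3 at 0.623, 0.396 and 0.389 with an estimated correlation as well. In cytoplasmic RNA they did so for immediate early genes (0.0441 to 0.0698).

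**Figure D3:**
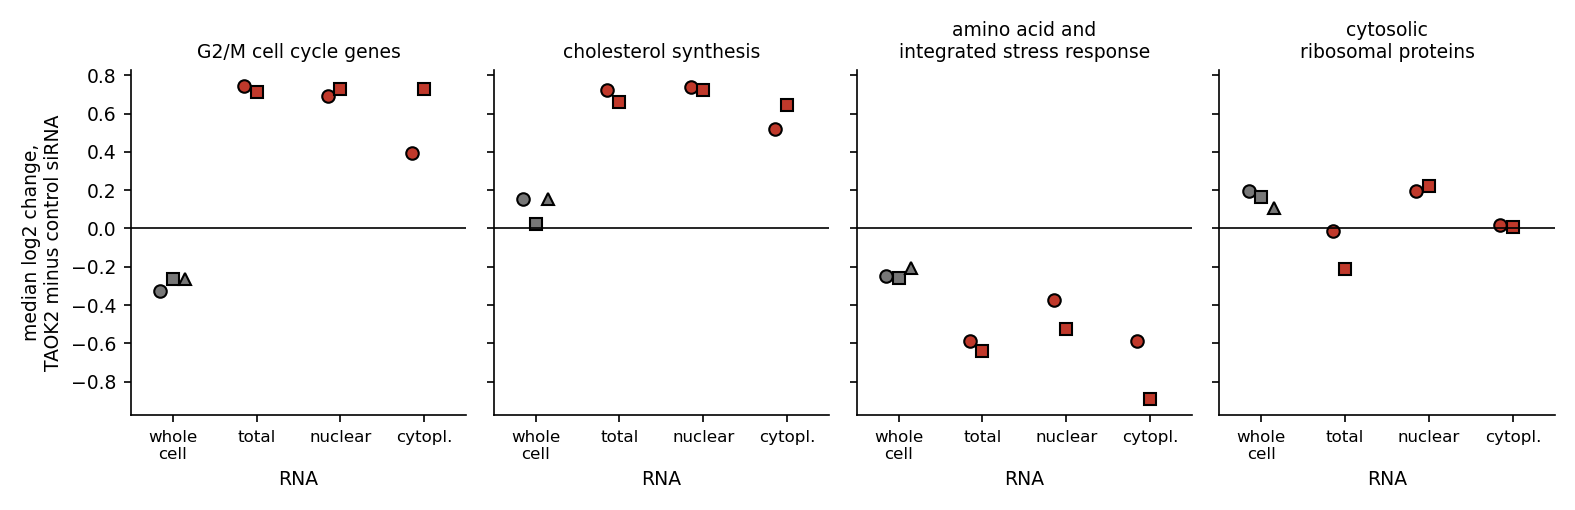
Median log2 change of 4 gene lists under TAOK2 knockdown (vertical axis) within each batch, in whole cells (grey, batches A, B and C) and in total, nuclear and cytoplasmic RNA (red, batches 1 and 2), with each symbol a batch. The G2/M median lies below 0 in the 3 whole-cell batches and above 0 in both batches of every fraction.

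The effect of knockdown on the ratio of nuclear to cytoplasmic RNA asked whether any RNA moved between the compartments. ERH, a small nuclear factor, had a ratio change of 0.62 ± 0.21 and MARF1, an RNA-binding protein, of 1.11 ± 0.37, with adjusted p = 1.000 and 1.000. The other genes with the smallest p, FTH1P15, UBE2Q2P1, CCDC162P and COMMD3-BMI1, had changes of 1.70, -1.38, -1.03 and -2.04. Limma passed 0 of 13751 genes (184 at an unadjusted p of 0.05), and 0 with batch as a block (787). By camera, which compares a list with all other genes, speckle and SR protein genes stood lower, towards the cytoplasm, with a median of -0.28 (adjusted p = 0.000258, and 0.555 with an estimated correlation). Detained-intron genes did so at -0.23 (adjusted p = 0.000980, and 0.594 with an estimated correlation), and 0 members of either list passed adjusted over the list alone (2 lower in each with the block). Hypoxia genes stood higher, towards the nucleus, with a median of 0.36 (adjusted p = 0.000258, and 0.537 with an estimated correlation). Respiratory chain genes did so at 0.20 (adjusted p = 0.000281, and 0.0882 with an estimated correlation) and core spliceosome genes at 0.20 (adjusted p = 0.00164, and 0.537 with an estimated correlation). Camera called 12 lists, 0 with an estimated correlation, and fry called 0. With the block G2/M genes (0.183 to 0.0409), NRF2 targets (0.0618 to 0.0266) and secreted protein genes (0.0618 to 0.0266) were called as well, but not with an estimated correlation (0.768, 0.526 and 0.526).

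The share of TPM in transcripts annotated as retaining an intron measured processing across the transcriptome. In nuclear RNA it was 7.68 ± 0.471% against 9.30 ± 0.627% (SD, n = 2), lower after knockdown in both batches. The exact permutation p was 0.333, 2-sided, which is the smallest this design allows. Leaving out mitochondrial genes the nuclear shares were 12.5 ± 0.137% against 15.6 ± 0.214%. In total RNA it was 5.90 ± 0.495% against 5.89 ± 0.718% (exact p = 1), and in cytoplasmic RNA 3.61 ± 0.109% against 3.75 ± 0.237% (exact p = 0.667). Whole cells held 4.83 ± 0.194% against 4.69 ± 0.256% with knockdown (exact p = 0.4, with 0.1 the smallest possible, n = 3) and 4.61 ± 0.328% against 4.78 ± 0.116% with compound 2 (exact p = 0.4). The share in nonsense-mediated decay transcripts was 3.56 ± 0.0584% against 3.71 ± 0.170% with knockdown (exact p = 0.2) and 3.48 ± 0.126% against 3.70 ± 0.0830% with compound 2 (exact p = 0.1). In whole-cell usage under knockdown, the 5972 retained-intron transcripts had a median change of 0.08, 38.9% of them below 0. In nuclear usage, the 7730 such transcripts had a median change of -0.22, 72.1% of them below 0, and limma passed 0 of 41169 transcripts (1184 at an unadjusted p of 0.05).

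**Figure D4:**
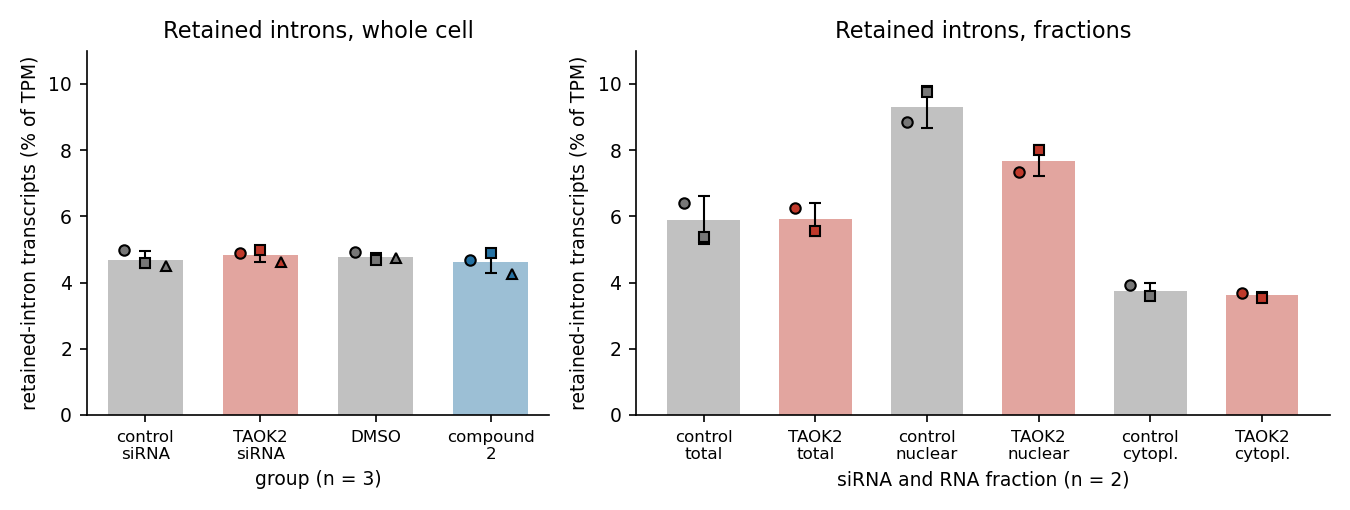
Percent of TPM in retained-intron transcripts (vertical axis) per library, by group on the horizontal axis, for whole cells (n = 3) and fractions (n = 2); bars are means, error bars the SD and symbols the batches. Nuclear RNA held 9.30% with control siRNA and 7.68% after knockdown.

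Comparing the knockdown between the experiments asked which changes recur. EMP1 and STC1 were higher after knockdown in whole cells (EMP1 1.62 and STC1 2.16) and, with batch as a block, in total RNA (EMP1 1.60 and STC1 1.47), and the integrated stress response list moved down in both (medians -0.23 and -0.61). Without TAOK2 siRNA total replicate 1 or 2, 0 genes passed in total RNA with the block. G2/M genes had a median of -0.32 in whole cells and 0.73 in total RNA. Across 12429 genes, which are not independent replicates, whole-cell changes correlated with those of total RNA at r = 0.322 (Spearman 0.303), and at 0.199 to 0.305 between single batches. The correlation was 0.178 with nuclear and 0.220 with cytoplasmic RNA. Of 2816 genes called in whole cells and tested in both, 71.7% had the same sign in total RNA. Without TAOK2 siRNA total replicate 2 the correlation with total RNA was 0.194.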

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

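Tests of the explanations for the G2/M pattern, for a fall of most other RNAs under compound 2 and for the nuclear retained-intron share were chosen after the result was seen. In 3 gene lists, every batch of one experiment moved one way under TAOK2 knockdown and every batch of the other experiment the opposite way; the differences themselves were not tested. The median change of G2/M genes was higher by 1.04 in total RNA than in whole cells (-0.33, -0.26 and -0.27 in batches A, B and C, and 0.74 and 0.71 in batches 1 and 2). DNA replication genes differed by 0.83 (-0.26, -0.27 and -0.19 in batches A, B and C, and 0.42 and 0.62 in batches 1 and 2). Cytosolic ribosomal protein genes differed by -0.30 (0.20, 0.16 and 0.11 in batches A, B and C, and -0.01 and -0.21 in batches 1 and 2), but with median-centred values batch 1 was 0.0185 and had the sign of the whole cells.

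Cell division genes therefore went down in whole cells and up in the fractionation experiment after the same siRNA. Library scaling was argued against, since with median-centred values the medians still lay 0.953 apart (-0.249 ± 0.0213 over whole-cell batches and 0.703 ± 0.103 over total RNA batches, SD). The list was flagged by the signs of its batch medians, so only their sizes count. A weaker knockdown in the fractionation experiment was argued against, since it would leave a smaller fall and the lower median of both batches of total RNA was 0.713 (SD over members 0.276). Of 41 members, 41 lay above 0 on average and 38 in both batches, short of a bound of 95% first set for that count. A batch that stands apart was argued against, since batch medians of both experiments lay at least 0.976 apart and ranged over at most 0.0640 within an experiment. What stays open is any difference between the experiments that both batches share. Cell density or time after transfection may differ, but is not given in the labels. The sample titles do differ: those of whole cells carry the word mock and those of the fractions do not. Whether this marks a different treatment was not tested. No biological explanation was tested.

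Under compound 2, 62 of the 172 genes that rose at least 2-fold were pseudogenes. Reads from introns of a host gene on the same strand may contribute to rises of genes with 1 or 2 exons. Such genes did not rise as a class: the 685 not inside a gene had a median change of -0.356, and all tested genes -0.314. Of genes with 1 or 2 exons, 36.7% of the 98 inside a longer tested gene on the same strand rose at least 2-fold, against 15.8% of 95 on the opposite strand and 3.80% of 685 not inside a gene (odds ratio 10.4 for the same strand against the others, 95% interval 6.01 to 18.1, Fisher's exact p = 3.46e-17; 3.08 against the opposite strand, exact p = 0.00108). Whether the libraries kept the strand of a read is not given in the sources used here, and the contrast between strands tells intron reads apart only if they did. EID3, the largest rise, is such a gene inside TXNRD1, whose own level was -0.473 by log2 change. Whether reads shared with a parent gene contribute was not settled. The parents of 40 pseudogenes had a median change of 0.113 (bootstrap SE 0.0704) where the pseudogenes had 1.99, so the parents did not rise alike. A parent far more abundant than its copy could pass a few reads to it and barely change itself. A fall of most other RNAs was argued against as the only cause. Alone, it would give the 172 genes that rose at least 2-fold 1 shared change within error. Their SD over genes was 0.760 and their median standard error 0.146. These genes were picked by the size of their rise, so the SD does not tell how much such a fall adds to each. A change in transcription past gene ends or in intron removal stays open as a biological explanation and was not tested.

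In nuclear RNA, the share in retained-intron transcripts was lower after knockdown in both batches. Cytoplasmic RNA carried over into the knockdown nuclear fractions may account for it: across 13751 genes, the nuclear change of a batch fell with the control nuclear to cytoplasmic ratio of the other batch, with slopes of -0.127 and -0.150. After that relation was removed, the median of the detained-intron list went from -0.33 and -0.27 to -0.018 and 0.0058. The same carry-over predicts the nuclear rise of respiratory chain and cytosolic ribosomal protein genes (medians 0.26 and 0.23), the most cytoplasmic lists. A transcript length bias was argued against, since the change did not rise with length (higher of both Spearman correlations -0.0479). A shift of nuclear RNAs out of the nucleus under knockdown predicts the same slope and stays open, as does a change of splicing.

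For comparisons of 3 against 3 libraries, 10 splits exist, too few for a share under 0.05. The real split and the highest other gave, for genes, 2905 against 0 under knockdown, 8354 against 0 under compound 2 and 843 against 0 between the controls; limma called 0 in the other splits. For transcript usage they gave 36 against 1 and 14224 against 1 under knockdown and compound 2. In each of these 5, 1 split, the real one, gave as many calls. For gene lists under compound 2 they gave 16 against 13 with 1 split as large, and under knockdown 15 against 16, with 4 of the 10 splits as large, the highest of those parting all 3 batch pairs giving 15. For the difference between knockdown and compound 2, 2 of 100 drawn splits, the real one included, gave as many calls as the real 7174. The highest, 7647, swapped TAOK2 siRNA with control siRNA in all 3 batches, which keeps both groupings and tests the sum of the effects. After the real split, the next highest gave 5815. These splits mix libraries within both pairs of groups, so an effect of compound 2 alone would set the real split apart. They therefore cannot tell whether the responses differ by more than chance.

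Transcripts matched to no gene, which no comparison above uses, carried signal relative to the controls: 23 of 1901 tested were higher after knockdown and 71 lower by limma. Under compound 2, 206 were higher and 639 lower.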

How the results depend on the processing

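Rescaling without mitochondrial genes, and the block combined with median-centring, rescaling, a pseudocount of 0.1, an estimated correlation or a library left out, were chosen after the results were seen. The counts of genes called under knockdown, under compound 2 and for their difference stayed within 1.5 times under all alternatives other than leaving out a library (10 for knockdown). The controls gave 416 with no filter, and 1543, 1599 and 1558 with batch as a block alone, median-centred and rescaled. Nuclear against cytoplasmic RNA in control cells gave 10884 with the block and rescaling. The cause of these changes was not tested.

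Counts in the fractions depended on the batch block, a term of the fit that takes out differences between batches. With the block, total, nuclear and cytoplasmic RNA gave 339, 811 and 404; median-centred 494, 1062 and 571; rescaled 374, 1310 and 466; with a pseudocount of 0.1 319, 593 and 449. Without the block they gave 1, 115 and 3 with no filter, 5, 10 and 3 median-centred, and 2, 7 and 11 rescaled. A filter at 5 TPM gave 7 nuclear and 5 cytoplasmic, and a pseudocount of 0.1 gave 1 cytoplasmic. Moderation without trend or robust settings gave 1 total and 7 nuclear, and only the compared groups gave 0 nuclear. The ratio gave 10 with no filter and 0 with the block, where limma had 787 genes at an unadjusted p of 0.05. Other than for the filter, which changes how many genes are tested, the cause was not tested.

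Transcript usage gave 18 under knockdown with a pseudocount of 0.1, and 65 and 5061 under knockdown and compound 2 with a filter at 5 TPM, which tests fewer transcripts. List calls with an estimated correlation went from 15 to 0 under knockdown, from 16 to 0 under compound 2 and from 62 to 13 over the fraction comparisons, 3 with the block as well. The nuclear retained-intron difference of -1.62 percent of TPM was -3.03 without mitochondrial genes. Apart from the block values given beside the results, the block changed no call of a reported list with the preset correlation.

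Leaving out each library gave 1678 to 2270 genes under knockdown, lowest without TAOK2 siRNA replicate 2, 117 to 825 for the controls, lowest without control siRNA replicate 2, 0 to 1 in nuclear RNA, 0 to 1 in cytoplasmic RNA and 0 to 1 for the ratio. Usage under knockdown gave 10 to 13. With the block as well, counts without TAOK2 siRNA replicates 1 and 2 and control siRNA replicates 1 and 2 were 0, 0, 276 and 18 in total, 13, 20, 23 and 18 in nuclear and 362, 1464, 26 and 7 in cytoplasmic RNA, against 339, 811 and 404; the ratio gave 2 without TAOK2 siRNA cytoplasmic replicate 2 and 1 without control siRNA nuclear replicate 2. The correlation of knockdown with compound 2 ran from 0.0362 to 0.0768, lowest without compound 2 replicate 2, and that between the experiments from 0.194 to 0.343, lowest without TAOK2 siRNA total replicate 2. In the fractions, leaving out a library leaves a group with 1 library, which is assumed to vary like the others.

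Some directions reversed. Median-centred, with and without the block, compound 2 changes were 0.047 for ATF4, 0.075 for LAMC1 and 0.034 for ABCA3, which did not pass, and the difference for ACTB, 0.0192 in the main fit, was -0.296 and passed (adjusted p = 0.0133, and 0.00315 with the block); with rescaling, with and without the block, AHSA1 was 0.038 between nucleus and cytoplasm. Median-centring shifts every gene of a library alike. Leaving out a library, the retained-intron difference of compound 2 ran from -0.317 to 0.00462, highest without compound 2 replicate 3. The cytoplasmic difference ran from -0.314 to 0.0221, highest without control siRNA cytoplasmic replicate 1, and the total difference, up to 0.522, was -0.336 without TAOK2 siRNA total replicate 1 and -0.494 without control siRNA total replicate 2. For nonsense-mediated decay the cytoplasmic difference, up to 0.450, was -0.0275 without control siRNA cytoplasmic replicate 1 and -0.164 without TAOK2 siRNA cytoplasmic replicate 2; the total difference, down to -0.155, was 0.135 and 0.0729 without TAOK2 siRNA total replicate 1 and control siRNA total replicate 2, and 0.0109 without mitochondrial genes. The cause was not tested.

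For single named genes, and the shares outside whole cells and nuclei, with a library left out, 9403 values kept their direction and side of the threshold, 442 fell short of it, 16 newly passed, 4 without a test moved and 7 reversed. With a library left out and the block, 4516 kept both and 336 newly passed. Under the other settings these numbers were 16147, 185, 1259, 1 and 11. The tables keep no read counts, so the limit that depth sets could not be computed.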

Other observations

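Further genes changed in whole cells within lists that were not called. Under knockdown, neuronal and microtubule genes MAP2, MAP1B and the tubulin TUBA1A rose and the centrosomal tubulin TUBG1 fell (MAP2 1.06, MAP1B 0.68, TUBA1A 0.81 and TUBG1 -0.59), with the cytoskeleton list at 4 up and 2 down of 34 (4 and 2 adjusted over the list alone) and not called (adjusted p = 0.0624 with the preset correlation and 0.575 with an estimated correlation). The airway basal factor TP63 and the progenitor factor SOX9 rose, the surfactant lipid transporter ABCA3 rose and FOXA2 fell (TP63 1.01, SOX9 1.03, ABCA3 0.49 and FOXA2 -0.52), with the alveolar and airway list at 3 up and 1 down of 13 (3 and 1 adjusted over the list alone) (adjusted p = 0.0624 with the preset correlation and 0.554 with an estimated correlation). The cholesterol transport gene STARD4 and the enzyme MSMO1 rose while CYP51A1 and TM7SF2 fell (STARD4 1.07, MSMO1 0.86, CYP51A1 -0.54 and TM7SF2 -0.92).

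Under compound 2, the Hippo pathway genes TEAD4 and WWC1 fell (TEAD4 -1.39 and WWC1 -1.22; YAP and TEAD targets 1 up and 15 down of 27 (1 and 15 adjusted over the list alone); adjusted p = 0.965 with the preset correlation and 0.989 with an estimated correlation). Among p53 targets (6 up and 14 down of 29 (6 and 15 adjusted over the list alone); adjusted p = 0.606 with the preset correlation and 0.909 with an estimated correlation), the death receptor TNFRSF10B fell and ZMAT3 rose (TNFRSF10B -1.97 and ZMAT3 1.65). The cholesterol list was not called (2 up and 6 down of 25 (2 and 6 adjusted over the list alone); adjusted p = 0.144 with the preset correlation and 0.838 with an estimated correlation). The liver and gut factor HNF4A (-1.62) and the tight junction gene OCLN (-1.58) fell. Minor spliceosome genes were 0 up and 8 down of 12 (1 and 9 adjusted over the list alone) (adjusted p = 0.837 with the preset correlation and 0.975 with an estimated correlation).

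The share of TPM in ribosomal RNA pseudogenes was 0.123% to 0.179% with compound 2 and 0.0195% to 0.0626% with DMSO. Compound 2 libraries held 12490 genes at 1 TPM or more on average, and DMSO libraries 13071. No test of these values was planned, and none was run.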
